A study of Homo sapiens with 12 samples.

How the data were processed

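Messenger RNA levels were measured by sequencing in human umbilical vein endothelial cells (HUVEC) in culture, left untreated or exposed for 3 h to poly(I:C), to thrombin or to both. Each of the 4 groups held 3 libraries, 12 in all, and every sample was placed in its group from its title. Per the labels' protocols, the cells were a commercial pool, total RNA was extracted with the Priazol method and libraries were made with the NEBNext Ultra RNA kit. The labels do not state whether the libraries kept strand, so reads of a gene and of an antisense or overlapping gene cannot be told apart here. Replicate numbers are shared between groups in the titles, and the labels do not say what a number marks.

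The authors deposited a table of counts per gene symbol, whole numbers with a different total in each library, which were treated here as rounded expected counts because Salmon is the only quantification tool in the submitters' processing notes. The authors also deposited a table of FPKM values, fragments scaled by gene length and library total, in which the length implied by count and FPKM differs between libraries for the same gene. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Salmon (no version), R 3.5.3, DESeq2 1.22.1 and the build GRCh38 were used, with no role or order given. The annotation release and any filter were not given in the sources used here. Both tables list 32835 gene symbols. Symbols were matched to GENCODE release 29 on GRCh38 for positions, and 31537 of them named exactly 1 gene there, so positions are printed only for such genes.

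Library totals lay between 7218252 and 16981938 counts. A count of 0 in 1 library allows up to 3 counts, a floor of 0.177 to 0.416 CPM (counts scaled to 1e+06 per library) depending on the library. Floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 2.503 to 21.26 between pairs of replicates, so all tests used a fitted spread between libraries.

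Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups with its default minimum count of 10 and minimum total count of 15, which kept 16116 genes holding 99.74% of all counts and removed 16719. Libraries were scaled by TMM factors, and all 12 were fitted in 1 quasi-likelihood model with a mean per group and no block, with 8 residual degrees of freedom. The biological coefficient of variation was 11.4%. Contrasts gave 5 pairwise comparisons and the interaction, the difference between the log2 effect of thrombin with poly(I:C) and without it. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Group levels are means of TMM-scaled CPM with their SD over 3 libraries. A gene with no count in any library of a group has a fold against the floor of 3 counts over that whole group.

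Before the data were examined, 31 gene lists and 38 focus genes were written down, together with the tests, the alternatives and the rule for named genes. The 31 lists comprised type I and III interferon genes, interferon-stimulated antiviral genes, double-stranded RNA sensing, NF-kB pathway and feedback, chemokines, inflammatory cytokines, leukocyte adhesion, procoagulant, anticoagulant, fibrinolysis, protease-activated receptors with their transducers, immediate early, SRF/MRTF and YAP/TAZ targets, endothelial junctions, vasoactive and KLF2/KLF4 genes, endothelial identity, MHC class I, cell death, p53 targets, cell cycle, unfolded protein response, cholesterol synthesis, hypoxia, mitochondrially encoded genes, ribosomal proteins, histones, and markers of mural, leukocyte, epithelial, erythroid and lymphatic endothelial cells. The 29 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists of a comparison. For each list the calls are given over all genes and adjusted over the list alone. Some genes stand in more than 1 list.

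The rule for named genes took, in the comparison of each single treatment with untreated cells, of both treatments with poly(I:C), and in the interaction, the 8 largest increases and the 6 largest decreases. They had to have an adjusted p under 0.05, a mean of at least 1 CPM, a symbol that is no clone name and, in pairwise comparisons, no overlap between the libraries of the compared groups. It added the focus genes and, for each list, up to 4 members with the smallest adjusted p. XIST and Y-linked genes were left out. Some genes that the rule named are not reported here.

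Further quantities were computed from the same fit. Genes induced by poly(I:C) were those called with a log2 fold change of at least 1. For genes raised at least 2-fold by each treatment alone and for the focus genes, the mean CPM with both treatments was compared with the sum of the separate effects (poly(I:C) plus thrombin minus untreated) and with their product (poly(I:C) times thrombin over untreated). The SE of the excess over the sum combined the SDs of the 4 groups. Comparisons that share libraries were set beside 20 simulated data sets made from the fitted means and spreads. Each gene was drawn independently in them, so deviations that libraries share across genes were left out.

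The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), DESeq2 1.42.0 as the test, no low-count filter or at least 1 CPM in 3 libraries, thinning to the smallest total, the replicate number as a block, only the compared groups in the fit, stricter thresholds, each library left out in turn, and limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 for a mean FPKM of at least 0.5 or with no filter. After seeing the data 3 more were added, namely 8 libraries (without the library of each group that lay lowest on the first within-group axis), the length per gene and library implied by the deposited tables as an offset, and the log2 CPM in olfactory receptor genes as a covariate. Olfactory receptor genes, 395 in the table, were taken as genes that endothelial cells are not known to need, as a measure of background reads. The first within-group axis is the first principal component of log2 CPM after the group means were removed, over 11575 genes with a mean count of at least 50.

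The test was checked on simulated data with known changes. For poly(I:C) versus untreated, edgeR recovered 40.3% of 1.5-fold, 71.6% of 2-fold and 98.5% of 4-fold changes and called 9 other genes among 15869 tested. For the interaction it recovered 53% of 2-fold and 85% of 4-fold changes and called 5 other genes among 15869 tested.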

Results

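Gene expression was measured in 12 libraries of pooled primary endothelial cells from the umbilical vein, 3 untreated, 3 with poly(I:C), 3 with thrombin and 3 with both (called combined below). Poly(I:C) is a synthetic double-stranded RNA that stands in for viral RNA, and thrombin is the protease of coagulation that also signals through protease-activated receptors. The series asks whether thrombin amplifies the inflammatory and coagulant response of these cells to poly(I:C). Total counts were 7218252, 12177012 and 10140324 in untreated replicates 1 to 3, and 11141414, 12223092 and 10897704 with poly(I:C). They were 12154032, 10422768 and 11229385 with thrombin and 9384800, 11052469 and 16981938 with both. Counts of 16116 genes were tested, adjusted p values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these genes, and those of gene lists are from camera over 29 lists.

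The libraries differed within groups along a shared direction. The first axis of the within-group deviations held 45% of their variance, and untreated replicate 3, thrombin replicate 2 and combined replicate 1 stood lowest on it, with scores of -9.99, -18.2 and -23.2 against -3.56 to 13.6 in the other 9. Counts in olfactory receptor genes, a measure of background reads chosen after seeing the data, were 874 to 1602 CPM in the combined libraries and 580 to 906 CPM in the other 9. Mitochondrially encoded genes held 1.47% of counts in poly(I:C) replicate 3 and 2.32% to 3.32% in the other 11 libraries.

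**Figure D1:**
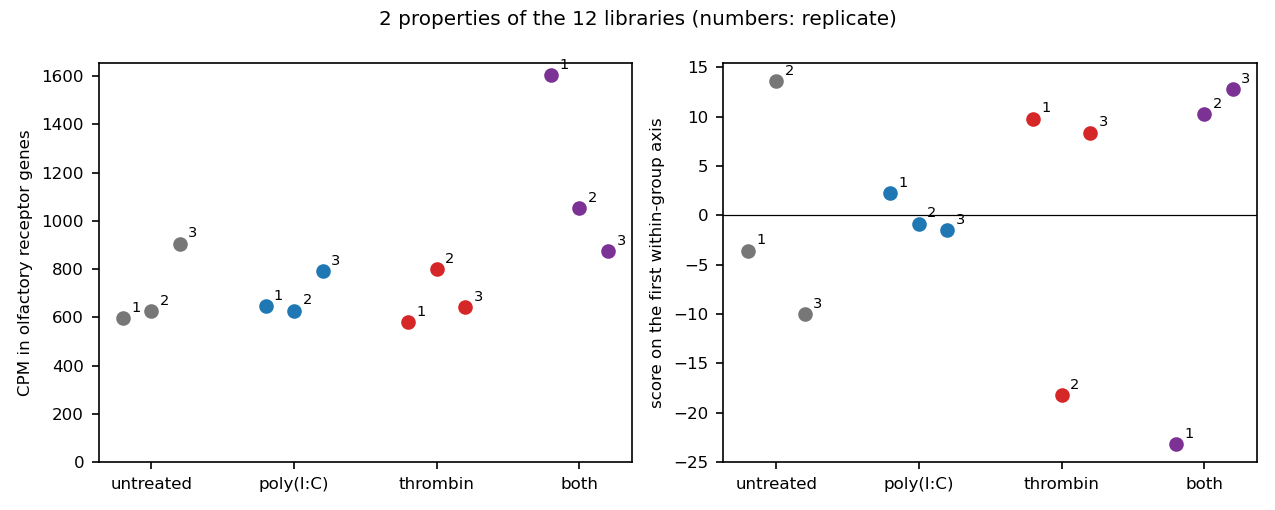
CPM in olfactory receptor genes (left) and the score on the first within-group axis (right, no unit) are plotted for each of the 12 libraries by group, 1 point per library with its replicate number. Combined replicate 1 has the highest olfactory receptor level, 1602 CPM, and the lowest score, -23.2.

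Poly(I:C) alone raised chemokine, adhesion molecule and antiviral genes. CXCL10, which encodes a chemokine for activated T cells (chromosome 4, 76021117 to 76023497, GRCh38), had a level of 0.282 ± 0.28 CPM (SD, n = 3) in untreated cells and 9.56 ± 4.15 CPM with poly(I:C). The increase was 38.1-fold (log2 fold change 5.25 ± 0.55, SE, edgeR adjusted p = 5.76e-05). SELE, which encodes E-selectin (chromosome 1, 169722641 to 169764705), rose 12.4-fold from 15.4 ± 0.756 to 192 ± 37.8 CPM (edgeR adjusted p = 1.08e-08). VCAM1, another endothelial receptor for leukocytes, rose 9.03-fold from 12.6 ± 0.975 to 114 ± 30.4 CPM. The antiviral gene OASL rose 7.82-fold, IFIT2 5.47-fold, the cytokine gene LTB 5.49-fold, the chemokine gene CXCL2 5.29-fold and the NF-kB inhibitor gene TNFAIP3 5.09-fold. The decreases were smaller, with log2 fold changes of -0.88 ± 0.13 (SE) for ARRDC3, -0.77 ± 0.12 for GCNT1 and -0.76 ± 0.11 for the chemokine receptor gene CXCR4.

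In all 129 genes passed the threshold with poly(I:C), 111 higher and 18 lower, and 56 of them changed at least 2-fold. For each of the 129 the libraries of both groups did not overlap. This adds no separate support, since the genes were called on these same libraries. Of 47 interferon-stimulated antiviral genes, 18 rose, 0 fell and 29 did not pass (27 and 0 adjusted over the list alone). Their median log2 fold change was 0.816 with a camera adjusted p of 7.26e-37, against an adjusted p = 0.0396 with an estimated correlation. Among them were ZC3HAV1 (2.57-fold), IFI44 (4.36-fold) and IFIT1 (3.79-fold), while MX1 (log2 fold change 1.40 ± 0.38, SE, edgeR adjusted p = 0.17) and ISG15 (1.57 ± 0.81, 0.695) did not pass. Of 22 genes of double-stranded RNA sensing and interferon signalling, 6 rose and 0 fell (12 and 0 adjusted over the list alone), camera adjusted p = 1.81e-15 and adjusted p = 0.0134 with an estimated correlation. DDX58, the sensor RIG-I, was 3.24-fold and IRF1 2.80-fold higher. TLR3, which encodes the endosomal sensor of double-stranded RNA, had a log2 fold change of -0.26 ± 0.24 (SE, edgeR adjusted p = 0.844), and the interferon gene IFNB1 had too few counts to be tested. The NF-kB list had 17 of 27 genes higher and 0 lower (23 and 1 adjusted over the list alone), median 0.623, camera adjusted p = 3.75e-52 and adjusted p = 0.00068 with an estimated correlation. NFKBIA was 2.50-fold and BIRC3 3.23-fold higher. Of 15 chemokines, 9 rose and 0 fell (11 and 1 adjusted over the list alone), median 1.5, camera adjusted p = 3.23e-21 and adjusted p = 0.0193 with an estimated correlation. CCL2 was 4.10-fold, CX3CL1 4.58-fold and CXCL8 3.52-fold higher. Reads of CXCL1, CXCL2 and CXCL3, and of IFIT, OAS and GBP family members, may be shared between near-identical copies, so single members of these families are uncertain.

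Adhesion molecules had 3 of 16 genes higher and 0 lower (3 and 0 adjusted over the list alone), namely SELE, VCAM1 and ICAM1 (3.98-fold), camera adjusted p = 3.26e-06 and adjusted p = 0.0493 with an estimated correlation. Inflammatory cytokines had 3 of 19 higher and 0 lower (5 and 0 adjusted over the list alone), with CSF1 2.43-fold higher, camera adjusted p = 0.000108 and adjusted p = 0.054 with an estimated correlation. Immediate early genes had 4 of 32 higher and 0 lower (10 and 2 adjusted over the list alone), with ATF3 2.73-fold and JUNB 2.33-fold higher, camera adjusted p = 2.19e-09 and adjusted p = 0.164 with an estimated correlation. Coagulation genes moved little with poly(I:C) alone. F3, which encodes tissue factor, the initiator of coagulation, had a log2 fold change of 0.44 ± 0.18 (SE, edgeR adjusted p = 0.551, and 0.0454 over the 38 focus genes). THBD, which encodes the anticoagulant receptor thrombomodulin, had -0.35 ± 0.11 (edgeR adjusted p = 0.319, and 0.0159 over the focus genes). The 11 fibrinolysis genes had a median log2 fold change of -0.0239 and a camera adjusted p of 0.389. None of 15 procoagulant genes and none of 14 anticoagulant genes passed in edgeR or adjusted over the list alone. The camera adjusted p was 0.978 for the first and 0.0491 for the second at a median of -0.143, against an adjusted p = 0.459 with an estimated correlation. The 21 genes of protease-activated receptors and their transducers had 0 calls (2 higher and 0 lower adjusted over the list alone), camera adjusted p = 0.105. The PAR2 gene F2RL1 had a log2 fold change of 0.40 ± 0.09 (SE, edgeR adjusted p = 0.0689). Among the 38 focus genes, of which 36 were tested, 11 rose and 0 fell (19 and 4 adjusted over the list alone).

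The count of 129 was 53 with the length offset, 37 to 40 in the FPKM table, and 198 with the olfactory receptor covariate. CXCL11, 3.52-fold higher, lost its call without untreated replicate 3 (highest edgeR adjusted p = 0.0753) or poly(I:C) replicate 1, and the camera call of the anticoagulant list ended without any of 6 single libraries, with an adjusted p up to 0.343 without poly(I:C) replicate 3.

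Thrombin alone raised single adhesion molecule and chemokine genes and the tissue factor gene. SELE rose 13.2-fold to 203 ± 17 CPM and VCAM1 9.98-fold to 126 ± 20.9 CPM (SD, n = 3), close to their levels with poly(I:C). CXCL8, which encodes the neutrophil chemokine interleukin 8, rose 7.57-fold from 87.9 ± 20.2 to 667 ± 166 CPM (log2 fold change 2.92 ± 0.21, SE, edgeR adjusted p = 5.51e-07). F3 (chromosome 1, 94529225 to 94541800) rose 5.63-fold from 3.33 ± 0.522 to 18.4 ± 2.83 CPM (log2 fold change 2.49 ± 0.15, SE, edgeR adjusted p = 1.41e-07). The receptor gene for cysteinyl leukotrienes, CYSLTR2, fell by 2.45 ± 0.17 (log2, SE), from 15.2 ± 2.31 to 2.78 ± 0.338 CPM.

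Thrombin called 619 genes, 442 higher and 177 lower, of which 136 changed at least 2-fold. The libraries did not overlap between the groups for 617 of them, which calling them on these libraries largely fixes. The largest increases also included the Wnt antagonist gene DKK2 (9.08-fold), PMCH (8.16-fold), the nuclear receptor genes NR4A2 (7.13-fold) and NR4A1 (7.10-fold) and the survival gene BCL2A1 (6.59-fold). Other large decreases were those of STAT4 (log2 fold change -1.69 ± 0.32, SE), TRIL (-1.64 ± 0.18), FILIP1 (-1.58 ± 0.12) and the readthrough gene GIMAP1-GIMAP5 (-1.52 ± 0.29), whose reads cannot be told from those of its neighbours. THSD8 had no count in the 3 thrombin libraries and 1.78 ± 1.42 CPM in untreated cells, a mean 20.1 times the floor of 3 counts over the group. Its untreated counts were 23, 21 and 4, so the size of its fall is uncertain. Its call ended without any of 3 single libraries, with an edgeR adjusted p up to 0.0787 without untreated replicate 1.

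The NF-kB list had 16 of 27 genes higher and 0 lower with thrombin (24 and 0 adjusted over the list alone), median 0.578, camera adjusted p = 7.79e-30 and adjusted p = 0.00506 with an estimated correlation. BIRC3 was 4.17-fold and TNFAIP3 2.87-fold higher. Of 15 chemokines 7 rose and 0 fell (8 and 0 adjusted over the list alone), median 1.23, camera adjusted p = 9.39e-11 and adjusted p = 0.0924 with an estimated correlation. CCL20 was 6.01-fold, CXCL3 4.55-fold, CXCL1 3.89-fold and CCL2 2.75-fold higher, while CXCL10 had a log2 fold change of -0.92 ± 1.16 (SE, edgeR adjusted p = 0.891). Immediate early genes had 12 of 32 higher and 1 lower (15 and 1 adjusted over the list alone), camera adjusted p = 3.32e-10 and adjusted p = 0.164 with an estimated correlation. Inflammatory cytokines had 5 of 19 higher and 2 lower (6 and 3 adjusted over the list alone), camera adjusted p = 0.0189 and adjusted p = 0.214 with an estimated correlation. PTGS2, which encodes a cyclooxygenase, was 4.65-fold, IL11 4.46-fold and IL6 2.21-fold higher. Adhesion molecules had 3 of 16 higher and 0 lower (4 and 1 adjusted over the list alone), camera adjusted p = 0.00066 and adjusted p = 0.164 with an estimated correlation. Antiviral genes had 1 of 47 higher and 2 lower (1 and 2 adjusted over the list alone), median -0.13, camera adjusted p = 0.0441 and adjusted p = 0.674 with an estimated correlation. Of 22 genes of double-stranded RNA sensing and interferon signalling, 2 were higher (5 adjusted over the list alone), with a median of 0.0844 and a camera adjusted p of 0.139.

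Among coagulation genes, fibrinolysis genes rose with thrombin as a list, 5 of 11 higher and 0 lower (8 and 0 adjusted over the list alone), median 0.433, camera adjusted p = 3.61e-07 and adjusted p = 0.0259 with an estimated correlation. They go in opposite functional directions, since PLAU, the plasminogen activator urokinase (1.44-fold), rose beside SERPINB2, an inhibitor of it (2.11-fold). Of 14 anticoagulant genes 4 rose and 0 fell (5 and 1 adjusted over the list alone), camera adjusted p = 0.0195 and adjusted p = 0.32 with an estimated correlation. EXT1 was 1.85-fold, TFPI2 1.51-fold and THBD 1.42-fold higher. F3 was the only call among 15 procoagulant genes (2 higher and 0 lower adjusted over the list alone), camera adjusted p = 0.128, and VWF had a log2 fold change of 0.04 ± 0.20 (SE, edgeR adjusted p = 0.979). Of 21 genes of protease-activated receptors and their transducers 1 rose and 2 fell (2 and 2 adjusted over the list alone), camera adjusted p = 0.231. RGS2, a regulator of G protein signalling, was 3.5-fold higher, the PAR2 gene F2RL1 fell by 0.38 ± 0.09 and the PAR1 gene F2R fell by 0.33 ± 0.08 (log2, SE, edgeR adjusted p = 0.0332 and 0.0366). In all 15 of 36 tested focus genes rose and 2 fell (16 and 3 adjusted over the list alone).

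The count of 619 was 161 with the length offset, 96 to 115 in the FPKM table, 410 without untreated replicate 1 and 400 without thrombin replicate 1. The calls of F2RL1, F2R and THBD ended without 7, 9 and 2 single libraries, with an edgeR adjusted p up to 0.185 and 0.0975 for F2RL1 and THBD, both without thrombin replicate 1, and up to 0.144 for F2R without untreated replicate 2. The camera call of the antiviral list ended without 4 single libraries, with an adjusted p up to 0.73 without untreated replicate 1.

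**Figure D2:**
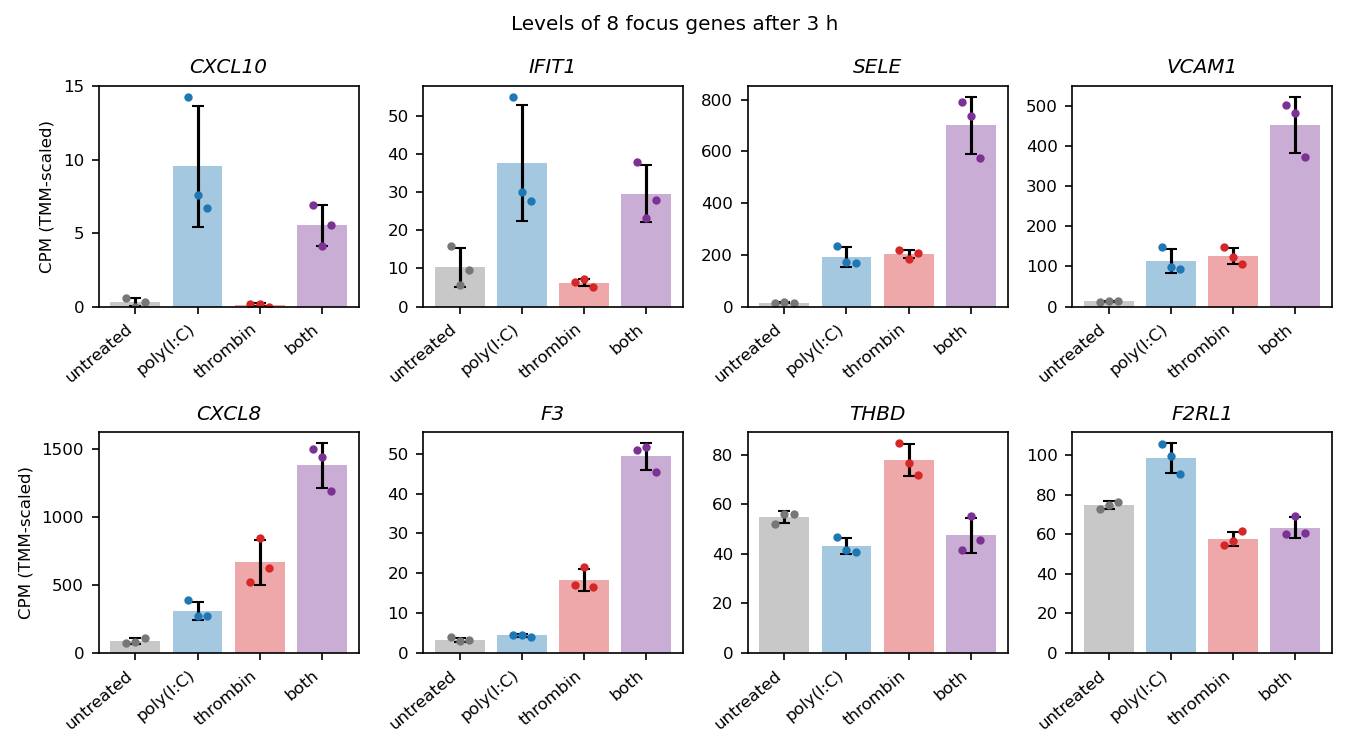
Bars give the mean TMM-scaled CPM of 8 focus genes in the 4 groups, error bars the SD and points the 3 libraries of each group, on axes that start at 0. F3 stands at 49.5 CPM with both treatments against 18.4 CPM with thrombin and 4.42 CPM with poly(I:C), while CXCL10 stands at 5.55 CPM with both and 9.56 CPM with poly(I:C).

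Adding thrombin to poly(I:C) raised F3 and 19 of 27 genes of the NF-kB list above their levels with poly(I:C) alone, and the antiviral genes did not pass as a list. F3 rose 11.2-fold from 4.42 ± 0.287 to 49.5 ± 3.38 CPM (SD, n = 3, log2 fold change 3.48 ± 0.14, SE, edgeR adjusted p = 1.58e-09). CXCL8 rose 4.47-fold from 310 ± 69.3 to 1383 ± 165 CPM, VCAM1 3.98-fold from 114 ± 30.4 to 455 ± 71.2 CPM. SELE rose 3.67-fold from 192 ± 37.8 to 702 ± 112 CPM and IL6 3.10-fold from 8.39 ± 0.837 to 26.1 ± 1.94 CPM. CXCL10, at 5.55 ± 1.41 CPM with both, had a log2 fold change of -0.78 ± 0.33 (SE, edgeR adjusted p = 0.195).

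The comparison of both treatments with poly(I:C) called 759 genes, 453 higher and 306 lower, 132 of them at least 2-fold. Of these calls, 757 had no overlap between the groups, which the selection of called genes largely fixes. Other large increases were CD248 (10.2-fold, from 0.178 ± 0.235 CPM with poly(I:C)), DKK2 (9.25-fold), NR4A1 (8.90-fold), BCL2A1 (8.55-fold), PMCH (7.35-fold) and NR4A2 (6.03-fold). Large decreases were those of CYSLTR2 (log2 fold change -2.10 ± 0.15, SE), TRIL (-1.74 ± 0.20), GDF7 (-1.43 ± 0.17), SIX2 (-1.43 ± 0.24) and the gap junction gene GJA4 (-1.29 ± 0.15). The readthrough gene PPAN-P2RY11 was at -1.34 ± 0.36 (edgeR adjusted p = 0.0461), and its call ended without any of 6 single libraries, with an adjusted p up to 0.194 without poly(I:C) replicate 2.

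The NF-kB list had 19 of 27 genes higher and 0 lower with thrombin added (21 and 0 adjusted over the list alone), median 0.523, camera adjusted p = 1.4e-18 and adjusted p = 0.026 with an estimated correlation. BIRC3 was 2.67-fold and SOD2 2.25-fold higher. Of 15 chemokines 7 rose and 0 fell (8 and 0 adjusted over the list alone), median 0.883, camera adjusted p = 4.9e-08 and adjusted p = 0.224 with an estimated correlation. CCL20 was 4.10-fold, CXCL2 3.79-fold and CXCL3 3.68-fold higher. Immediate early genes had 12 of 32 higher and 1 lower (15 and 1 adjusted over the list alone), camera adjusted p = 6.64e-08 and adjusted p = 0.313 with an estimated correlation. Inflammatory cytokines had 4 of 19 higher and 2 lower (5 and 2 adjusted over the list alone), with PTGS2 3.87-fold higher, camera adjusted p = 0.0255 and adjusted p = 0.317 with an estimated correlation. Adhesion molecules had 3 of 16 higher and 0 lower (3 and 0 adjusted over the list alone), with a median of -0.0437 but a mean of 0.275 and a camera adjusted p = 0.321. Antiviral genes had 2 of 47 higher and 1 lower (2 and 1 adjusted over the list alone), median -0.198, camera adjusted p = 0.106, and IFIT1 had a log2 fold change of -0.34 ± 0.28 (SE, edgeR adjusted p = 0.496). The 22 genes of double-stranded RNA sensing had a median of -0.0558 and a camera adjusted p of 0.335.

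Among coagulation genes, fibrinolysis genes had 4 of 11 higher and 0 lower with thrombin added (5 and 0 adjusted over the list alone), camera adjusted p = 0.000377 and adjusted p = 0.136 with an estimated correlation. SERPINB2 was 2.16-fold and PLAU 1.43-fold higher. Anticoagulant genes had 3 of 14 higher and 0 lower (5 and 0 adjusted over the list alone), camera adjusted p = 0.197, and THBD had a log2 fold change of 0.14 ± 0.11 (SE, edgeR adjusted p = 0.485). F3 was the only call of 15 procoagulant genes (1 and 0 adjusted over the list alone), camera adjusted p = 0.321. Protease-activated receptors and their transducers had 1 of 21 higher and 3 lower (1 and 6 adjusted over the list alone), median -0.198, camera adjusted p = 0.00168 and adjusted p = 0.317 with an estimated correlation. F2RL1 fell by 0.64 ± 0.09 and F2R fell by 0.48 ± 0.08 (log2, SE, edgeR adjusted p = 0.000778 and 0.00332), while RGS2 was 3.62-fold higher. Among 36 tested focus genes 15 rose and 3 fell (17 and 4 adjusted over the list alone). The combined libraries also had more olfactory receptor counts, 1176 ± 380 against 690 ± 90.4 CPM (SD, n = 3). The 1086 tested genes with a mean under 1 CPM had a median log2 fold change of 0.369 in this comparison.

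The count of 759 was 122 with the length offset, 70 to 84 in the FPKM table, 381 with the olfactory receptor covariate, 370, 279 and 386 without poly(I:C) replicates 1, 2 and 3, and 504 without combined replicate 2. The share of higher genes was 59.7%, against 46.4% of 964 with DESeq2 and 79.5% of 381 with the covariate. ICAM1 (1.70-fold) and TFPI2 (1.51-fold) lost their calls without poly(I:C) replicate 2 or 3, and CCL2 (1.84-fold) also without combined replicate 1. The edgeR adjusted p reached 0.0618, 0.0644 and 0.0763 without poly(I:C) replicate 2.

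**Figure D3:**
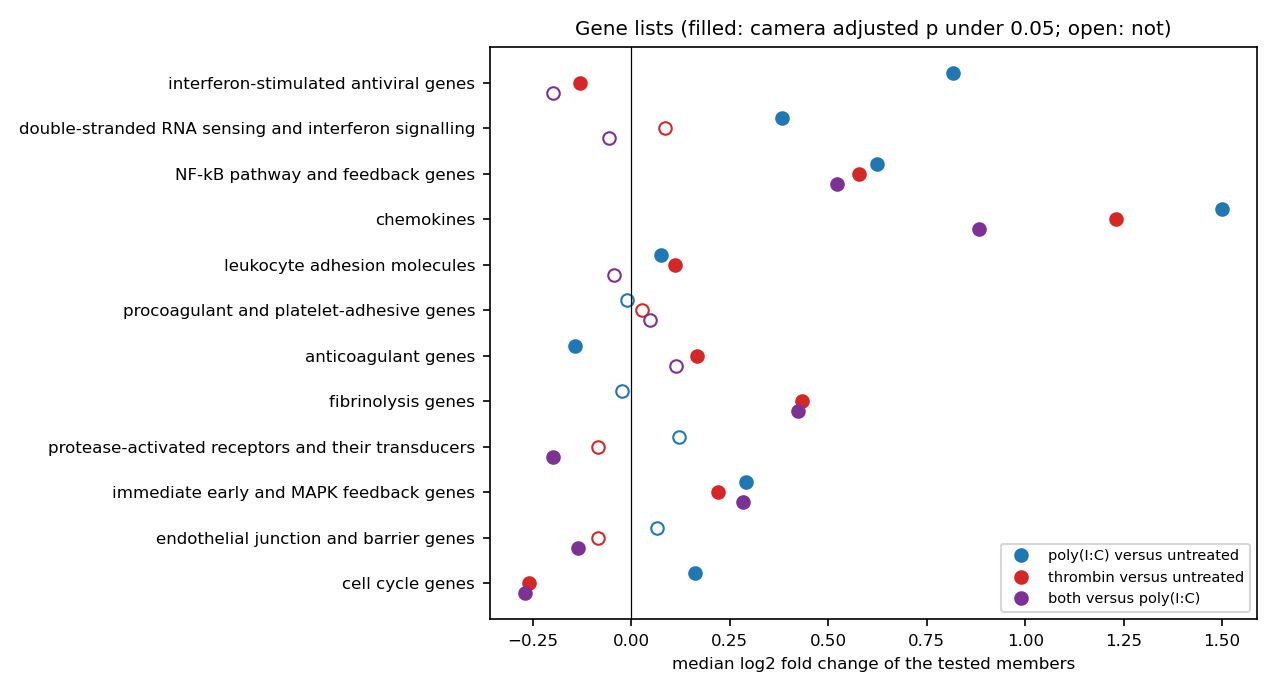
Points give the median log2 fold change (horizontal axis) of the tested members of 12 gene lists in 3 comparisons, filled where the camera adjusted p was under 0.05 at the preset correlation. The antiviral list stands at 0.816 with poly(I:C) and at -0.198 when thrombin is added to it, and the NF-kB list at 0.623, 0.578 and 0.523.

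Against untreated cells, both treatments together raised single adhesion molecule genes, CXCL8 and F3. SELE was 45.6-fold, VCAM1 36.0-fold, CXCL8 15.7-fold, F3 15.1-fold and ICAM1 6.77-fold higher, with edgeR adjusted p values of 6.03e-11, 8.27e-10, 1.62e-08, 4.06e-10 and 2.66e-08. In all 1105 genes passed, 630 higher and 475 lower, 225 at least 2-fold. Of these calls, 1096 had no overlap between the groups, which the selection of called genes largely fixes. The NF-kB list had 24 of 27 genes higher and 0 lower (26 and 1 adjusted over the list alone), camera adjusted p = 7.66e-46 and adjusted p = 0.00113 with an estimated correlation. Adhesion molecules had 3 of 16 higher and 0 lower (4 and 2 adjusted over the list alone), camera adjusted p = 0.00904 and adjusted p = 0.222 with an estimated correlation. F2R fell by 0.53 ± 0.08 and TFPI, an inhibitor of tissue factor, fell by 0.41 ± 0.09 (log2, SE, edgeR adjusted p = 0.000738 and 0.0115). Among 36 tested focus genes 19 rose and 3 fell (19 and 5 adjusted over the list alone). The count of 1105 was 330 with the length offset, 199 to 223 in the FPKM table, 611 with only these groups in the fit, 644 without untreated replicate 1 and 663 without untreated replicate 2. Higher genes made up 57%, against 48.8% of 1270 with DESeq2 and 74.1% of 878 with the covariate.

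Poly(I:C) added to thrombin raised 19 of 27 NF-kB genes and 18 of 47 antiviral genes and lowered the thrombomodulin gene. CXCL10 was 41.9-fold higher than with thrombin alone (log2 fold change 5.39 ± 0.63, SE, edgeR adjusted p = 0.000254), IFIT1 4.75-fold, VCAM1 3.60-fold, SELE 3.45-fold, TNFAIP3 3.03-fold, ICAM1 3.03-fold and F3 2.68-fold. THBD fell by 0.71 ± 0.11 (log2, SE, edgeR adjusted p = 0.0026). In all 217 genes passed, 142 higher and 75 lower, 60 at least 2-fold. Of these calls, 216 had no overlap between the groups, which the selection of called genes largely fixes. Antiviral genes had 18 of 47 higher and 0 lower (30 and 0 adjusted over the list alone), camera adjusted p = 9.85e-26 and adjusted p = 0.128 with an estimated correlation. The NF-kB list had 19 of 27 higher and 0 lower (22 and 0 adjusted over the list alone), camera adjusted p = 8.89e-31 and adjusted p = 0.00494 with an estimated correlation. Of 15 chemokines 9 rose and 0 fell (13 and 0 adjusted over the list alone), camera adjusted p = 2.76e-14 and adjusted p = 0.0934 with an estimated correlation. Anticoagulant genes had 0 of 14 higher and 2 lower (1 and 2 adjusted over the list alone), camera adjusted p = 0.0263 and adjusted p = 0.487 with an estimated correlation. Among 36 tested focus genes 14 rose and 1 fell (19 and 3 adjusted over the list alone). The count of 217 was 37 with the length offset, 34 to 42 in the FPKM table, and 87 with the olfactory receptor covariate. It was 90 with only these groups in the fit, 348 with no low-count filter, 477 with DESeq2 and 373 in 8 libraries, and 139 and 355 without combined replicates 1 and 3 and 92 and 106 without thrombin replicates 1 and 3. Of the 217 genes 65.4% were higher, against 50.3% with DESeq2 and 83.9% with the covariate.

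Of the 55 genes that poly(I:C) induced at least 2-fold, 27 rose further when thrombin was added, 0 fell and 28 did not pass. None of the 12 induced antiviral genes was called in either direction with thrombin added (edgeR), whereas 15 of 19 induced genes of the NF-kB and chemokine lists rose further. These shares differed (Fisher's exact test, two-sided, p = 1.61e-05, genes not being independent replicates). In 20 simulated data sets in which the combined group had the means of the poly(I:C) group, 0 induced genes were called in either direction. The selection uses the poly(I:C) libraries that also enter the comparison, and it gave 91 to 119 induced genes in those data sets. The 27 became 13 with the length offset.

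The interaction asks whether the effect of thrombin differs with poly(I:C) on the log scale. SELE was the only gene to pass, with an interaction of -1.85 ± 0.21 (log2, SE, edgeR adjusted p = 0.00364), since it rose 13.2-fold with thrombin alone and 3.67-fold when poly(I:C) was present. Over the 38 focus genes alone 5 passed, 2 higher and 3 lower, namely F3 at 0.99 ± 0.22 (edgeR adjusted p = 0.00457 over the focus genes and 0.538 over all genes) and EGR1 at 0.84 ± 0.26 (0.0413). Below 0 were SELE, VCAM1 at -1.32 ± 0.26 (0.00198) and TNFAIP3 at -0.75 ± 0.19 (0.0141). At an unadjusted level of 0.05 the interaction had 1153 genes against 805.8 expected by chance. The interaction was also above 0 in 92 of 94 tested olfactory receptor genes (median 0.739), so background reads in the combined libraries may add to the 1153. The interaction of the antiviral list had a median of 0.0862 and a camera adjusted p of 0.478, and that of chemokines -0.306 and 0.0734. DESeq2 called 5 genes, no low-count filter gave 7, the FPKM values 7 to 12 without SELE, and the length offset 0. SELE was at -1.56 to -1.74 (adjusted p = 0.074 to 0.12) with the FPKM values and at -1.72 (0.176) with the length offset. With 8 libraries 2 genes passed, SELE and 1 other, and the count was also 2 without untreated replicate 3, combined replicate 3 or thrombin replicate 3.

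On the scale of CPM, levels with both treatments were set against the sum and the product of the separate effects. F3 stood at 49.5 CPM with both, 2.54 times the sum (19.5 CPM, an excess of 11.7 SE) and 2.02 times the product (24.5 CPM). IL6 stood at 1.62 times the sum and 1.40 times the product, with an excess over the sum of 5.73 SE. THBD stood at 0.718 times the sum, 3.11 SE below it with an excess of -18.7 CPM. Of the 20 genes raised at least 2-fold by each treatment alone, 13 exceeded the sum by over 2 SE, 0 fell short of it by as much, and 19 lay below the product. The medians were 1.30 times the sum and 0.672 times the product. SELE was at 1.85 times the sum and 0.277 times the product, VCAM1 at 2.00 and 0.397, and CXCL8 at 1.56 and 0.589. The median interaction of the 20 genes was -0.57, against -0.46 to -0.00238 in 20 simulated data sets with exactly multiplicative effects. There each gene was drawn independently, and the same selection took 29 to 39 genes.

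**Figure D4:**
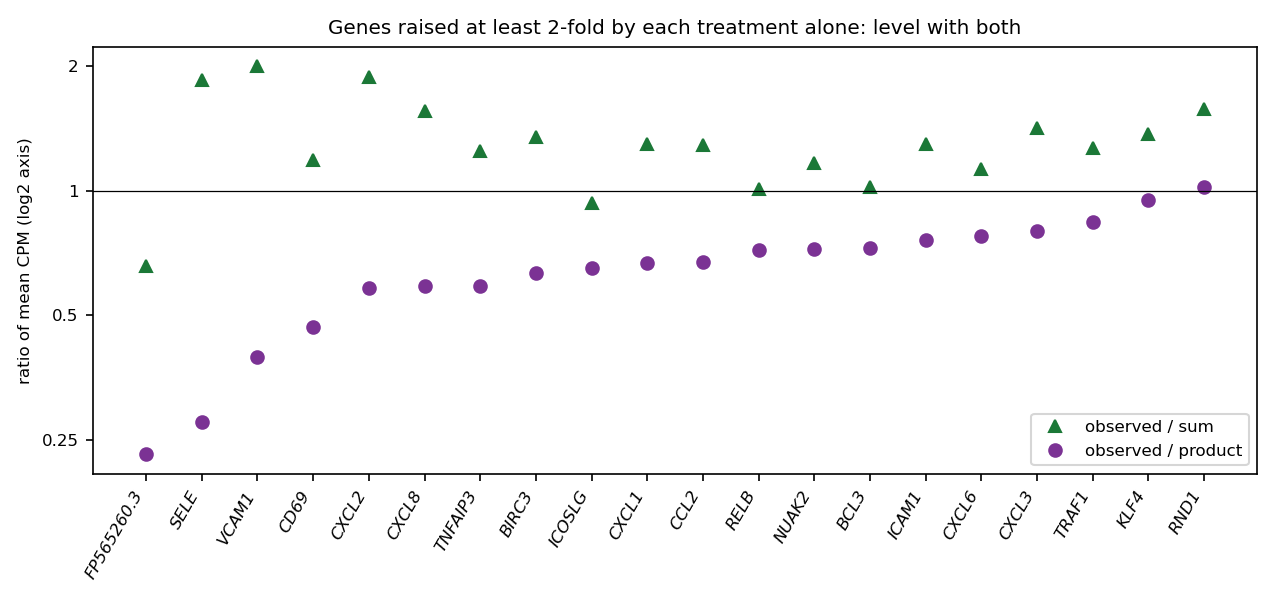
For each of the 20 genes raised at least 2-fold by each treatment alone, the mean CPM with both treatments is divided by the sum (triangles) and by the product (circles) of the separate effects, on a log2 axis. Ratios to the product lie below 1 for 19 genes, and the median ratio to the sum is 1.30.

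Genes called with thrombin alone mostly had the same sign of effect when poly(I:C) was present. Of 619 genes called with thrombin alone, 612 had the same sign when poly(I:C) was present, 362 were called in the same direction (244 higher and 118 lower, against 12.4 and 3.36 for independent lists) and 0 in the opposite direction. The slope of the effect with poly(I:C) on the effect without it was 0.552 over these 619 genes, which were selected on the latter. Across all 16116 genes the correlation of both effects was r = 0.191 with a covariance of 0.032, against -0.0337 to 0.0394 and -0.00241 to 0.00276 in 20 simulated data sets with no effect. It was 0.605 in 9699 genes with a mean of at least 10 CPM. The simulations drew each gene independently, so they lack the direction that the libraries share within groups. Their ranges may therefore be too narrow to judge the observed values by. Genes are not independent replicates, and r ranged from 0.0145 to 0.262 when single libraries were left out (jackknife SD 0.221).

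The responses to poly(I:C) and to thrombin shared called genes. In all 57 genes rose with each, 4 fell with each and 5 were called in opposite directions. The same untreated libraries enter both comparisons, while independent lists would share 3.04 and 0.198. In 20 simulated data sets with unchanged groups 0 to 1 gene was shared per direction. Those data sets held no changed genes to call, so they cannot show what the shared libraries add to lists of the observed size. The covariance of the effects was 0.0593 against 0.0343 to 0.0392 in the simulations, and r was 0.436 against 0.483 to 0.54. These ranges too come from genes drawn independently and may be too narrow. With 3 untreated libraries the controls could not be split, so part of the excess may come from them. The 61 genes shared in direction became 27 with the length offset and 93 with the olfactory receptor covariate.

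Other gene groups had some calls with thrombin, and none of their lists passed with an estimated correlation. Of 27 cell cycle genes 0 rose and 2 fell with thrombin alone (0 and 7 adjusted over the list alone), median -0.259, camera adjusted p = 1.43e-08 and adjusted p = 0.164 with an estimated correlation. AURKA, a mitotic kinase gene, had a log2 fold change of -0.58 ± 0.10 (SE). When thrombin was added to poly(I:C) 0 rose and 4 fell (0 and 14 adjusted over the list alone), camera adjusted p = 4.65e-09 and adjusted p = 0.224 with an estimated correlation. With poly(I:C) alone none passed (edgeR and over the list alone) at a median of 0.162 and a camera adjusted p of 0.000224, against an adjusted p = 0.375 with an estimated correlation. Of 18 genes of the unfolded protein and integrated stress response 7 rose and 0 fell with thrombin (8 and 0 adjusted over the list alone), camera adjusted p = 2.64e-09 and adjusted p = 0.0763 with an estimated correlation. When it was added to poly(I:C), 5 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 6.29e-05 and adjusted p = 0.23 with an estimated correlation). HERPUD1 was 1.49-fold higher with thrombin alone and 1.41-fold higher when it was added. Of 27 SRF/MRTF and YAP/TAZ targets 3 rose and 1 fell with thrombin (6 and 1 adjusted over the list alone), camera adjusted p = 2.53e-05 and adjusted p = 0.214 with an estimated correlation. Of 31 endothelial identity genes 5 rose and 3 fell (8 and 4 adjusted over the list alone), camera adjusted p = 0.0782, with SOX17 2.03-fold higher and SOX18 at a log2 fold change of -0.67 ± 0.12 (SE). Of 17 vasoactive and KLF2/KLF4 genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), camera adjusted p = 0.17, with KLF4 2.33-fold higher. Of 26 cell death genes 3 rose and 0 fell (6 and 2 adjusted over the list alone), camera adjusted p = 0.0156 and adjusted p = 0.273 with an estimated correlation. The apoptosis activator gene BCL2L11 was 1.95-fold higher. In this list 2 genes rose with poly(I:C) alone and 0 fell (4 and 0 adjusted over the list alone), camera adjusted p = 0.000306 and adjusted p = 0.138 with an estimated correlation. Of 17 hypoxia and glycolysis genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), camera adjusted p = 0.0257 and adjusted p = 0.375 with an estimated correlation. This camera call also ended without untreated replicate 3 or thrombin replicate 2 (adjusted p up to 0.09). Of 26 junction genes 0 rose and 2 fell with thrombin alone (0 and 4 adjusted over the list alone), camera adjusted p = 0.0671. When it was added to poly(I:C), 0 rose and 2 fell (0 and 3 adjusted over the list alone). The camera adjusted p was then 0.000458, against an adjusted p = 0.396 with an estimated correlation. Of 15 p53 targets 1 rose and 0 fell with thrombin alone (1 and 2 adjusted over the list alone), camera adjusted p = 0.626.

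With poly(I:C) alone, 1 of 20 MHC class I and antigen processing genes rose and 0 fell (2 and 0 adjusted over the list alone), namely TAP1 (1.77-fold), camera adjusted p = 0.00145 and adjusted p = 0.253 with an estimated correlation. None of 17 cholesterol synthesis, 13 mitochondrially encoded, 29 ribosomal protein and 8 replication-dependent histone genes passed in edgeR with poly(I:C) (1 cholesterol synthesis gene higher and none of the others adjusted over the list alone). The medians were 0.15, -0.297, -0.192 and -0.233 with camera adjusted p values of 0.00242, 0.000108, 7.34e-08 and 0.206, and an adjusted p = 0.459 with an estimated correlation for each of the first 3. The camera call of the MHC list ended without untreated replicate 2 (adjusted p = 0.0541), that of cholesterol synthesis without untreated replicate 3 (0.275) and that of mitochondrially encoded genes without poly(I:C) replicate 3 (0.927).

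Markers of other cell types gave few calls. With poly(I:C) none of 11 mural, 7 leukocyte, 8 epithelial, 5 lymphatic endothelial and 2 erythroid markers passed in edgeR (0, 0, 0, 0 and 0 higher, and 1 mural marker lower, adjusted over the list alone). The first 4 had camera adjusted p values of 0.898, 0.925, 0.206 and 0.425, and the last was too small to test. With thrombin the lymphatic list had RELN higher (3.04-fold, 2 higher adjusted over the list alone, camera adjusted p = 0.135). The epithelial list had KRT18 lower (log2 fold change -0.42 ± 0.09, SE, 1 lower adjusted over the list alone, camera adjusted p = 0.565). KRT18 is also expressed by these endothelial cells, at 326 ± 30.9 CPM when untreated, and its call ended without 4 single libraries, with an edgeR adjusted p up to 0.112 without untreated replicate 1. Of 7 interferon genes only IFNE was tested, and its log2 fold change was -0.04 with poly(I:C) and 0.95 ± 0.26 (SE, edgeR adjusted p = 0.0492) when thrombin was added to it. This call ended without 10 single libraries, with an adjusted p up to 0.205 without poly(I:C) replicate 2.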

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

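For the patterns weighed here, the tests on olfactory receptor genes, on thrombin alone and on transcript length were chosen only after the result was seen, as were the alternatives with 8 libraries, the length offset and the olfactory receptor covariate. A further condition was also added afterwards, that a bound counts only where the values of single libraries lie beyond it too, as was the use of all olfactory receptor genes in place of the tested ones.

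The effect of thrombin differed with and without poly(I:C) by the interaction test in 1 gene over all genes and in 5 focus genes over those alone. SELE (-1.85), VCAM1 (-1.32) and TNFAIP3 (-0.75) lay below the product of the separate effects, and F3 (0.99) and EGR1 (0.84) above it. By camera 7 lists differed, with median interactions of -0.158 for double-stranded RNA sensing, -0.0703 for NF-kB genes, -0.169 for adhesion molecules, -0.15 for protease-activated receptors and their transducers, -0.177 for endothelial identity genes, -0.221 for cholesterol synthesis genes and 0.215 for ribosomal protein genes (adjusted p = 0.0321, 0.0321, 0.00247, 0.0321, 0.0124, 0.00166 and 1.35e-05). With an estimated correlation and with fry none of the 7 passed (lowest adjusted p 0.646 and 0.521), against 7 with the preset correlation. With the olfactory receptor covariate the median interaction turned to 0.00483 for the receptors, 0.0338 for endothelial identity and -0.0152 for ribosomal protein genes. The other lists kept their direction. Leaving out single libraries ended the call of double-stranded RNA sensing in 5 cases (adjusted p up to 0.121, without poly(I:C) replicate 1), of NF-kB genes in 5 (up to 0.187, without thrombin replicate 2), of the receptors in 4 (up to 0.165, without combined replicate 1) and of endothelial identity genes without combined replicate 1 (0.302).

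Other splits of the libraries were refitted for each count. For the interaction, 5 of 100 splits drawn from 200 gave at least the 1 gene of the real split, so chance was not excluded for that count. The highest other split, with 1298 genes, exchanged the thrombin labels wholly in 1 background and so holds the effect of thrombin itself, and the highest of the remaining splits, with 206 genes, relabelled 2 libraries with poly(I:C) and 0 without it, so it holds part of that effect too. For each pairwise comparison there were only 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes in each, with 129, 619, 1105, 759 and 217 genes for poly(I:C), thrombin and both against untreated and for both against poly(I:C) and against thrombin, and the highest other split gave 2, 1, 2, 0 and 1.

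Weakly expressed genes were higher as a class with both treatments than with poly(I:C), with a median log2 fold change of 0.369 over 1086 tested genes under 1 CPM and 0.395 over 4518 genes of 0.25 to 1 CPM with no low-count filter. The median was 0.483 after thinning to equal totals, but the low-count filter was applied again to the thinned counts. A gene of this class then stayed only if it was high in some libraries, so this median cannot decide on library depth. At equal totals with no filter, 25145 to 26891 genes had a count in the combined libraries and 23622 to 24754 with poly(I:C). Those numbers cover all genes, not this class. An effect of thrombin in any background was argued against by -0.0238 in thrombin versus untreated. Combined replicate 1 as the only source stays open only by the condition added afterwards. The median was 0.233 without it, beyond the bound of 0.2 set beforehand against this explanation. Against the poly(I:C) mean, combined replicates 1 to 3 were at 0.612, 0.273 and 0.186, the last under that bound. Background reads from genes that the cells do not express may account for it, since the CPM summed over all 395 olfactory receptor genes, with no filter, was higher by a log2 ratio of 0.77 (874 to 1602 against 628 to 793 CPM) and the class median was -0.041 with that level as a covariate, which partly follows the combined group. Whether that background comes from genomic DNA, unspliced RNA or the treatment with both agents was not tested.

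Untreated replicate 3, thrombin replicate 2 and combined replicate 1 deviated from their groups in the same direction along an axis that held 45% of the within-group variance. Longer transcripts had higher loadings on this axis, with a Spearman rho of loading and length of 0.314 over 11575 genes. The median loading was -0.00417 in the shortest 10% of genes and 0.00719 in the longest 10%. The longest 10% of tested genes held 7.22% of counts in thrombin replicate 2 and 7.31% in combined replicate 1, the lowest of their groups. They held 7.49% in untreated replicate 3, against 7.28% and 8.55% in untreated replicates 1 and 2. The score also fell with the olfactory receptor level, r = -0.842 over 12 libraries (exact within-group permutation p = 0.0154, Spearman rho = -0.699 with permutation p = 0.0764, r = -0.695 without the 2 farthest libraries), so a difference in RNA quality or background reads may lie behind the axis. For GC content, a rho of 0.129 lay between the bounds set for and against it, which keeps it open. No biological explanation was tested, since the design gives no group that these 3 libraries share.

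The 20 genes raised at least 2-fold by each treatment alone fell short of the product of the separate effects, with a median interaction of -0.57. Scaling was argued against by a median of -0.49 or lower under the 3 other scalings, a single library by -0.458 or lower without any of the 12, and lengths per library by -0.621 with the length offset. Selection on shared untreated libraries alone gave medians down to -0.46 in 20 simulated data sets (mean -0.22, with 29 to 39 genes selected). The observed -0.57 lay below the lowest of these, the bound set beforehand against this explanation. It remains open by the condition added afterwards, because the values without single libraries reach -0.458. The simulations also drew each gene independently, so their range of medians may be too narrow. The shortfall was larger in genes with larger separate effects, rho = -0.795 against -0.445 to -0.0224 in the simulations. A negative rho is partly built in, since the interaction contains both separate effects with a minus sign. The simulated range for rho has the same limit of independent genes. A shared limit on these 20 genes therefore stays a hypothesis that this comparison cannot decide. F3, which poly(I:C) alone moved by 0.44 (log2), stood above the product, by an interaction of 0.99.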

How the results depend on the processing

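The alternatives with 8 libraries, a length offset and the olfactory receptor covariate were chosen after seeing the data, and every other alternative before. No named gene called in a comparison changed direction under any alternative. Of the values of named genes under the alternatives set beforehand 6204 stayed on their side of the threshold, 515 lost a call and 13 gained one, against 6594, 304 and 14 with single libraries left out and 1535, 175 and 17 under the later alternatives. For lists these numbers were 398, 60 and 6, then 1312, 45 and 33, then 189, 21 and 14. On simulated data of this depth, spread and number of libraries 40.3% of 1.5-fold and 71.6% of 2-fold changes were recovered, and thinning to the smallest total gave 137, 606, 995, 677, 233 and 1 genes. Except where fewer libraries or a stricter threshold explain it, the cause was not tested. Counts below are given in the order poly(I:C), thrombin and both against untreated, both against poly(I:C), both against thrombin, interaction, where not named.

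With the FPKM values 37, 96, 199, 70, 42 and 12 genes passed with no filter, 40, 115, 223, 77, 37 and 7 with a pseudocount of 0.1, and 39, 110, 213, 84, 34 and 8 with a pseudocount of 1. With the length offset the counts were 53, 161, 330, 122, 37 and 0 (edgeR), with 27 genes shared by poly(I:C) and thrombin and 13 induced genes raised further. With the olfactory receptor covariate 198 genes passed with poly(I:C), 381 for both against poly(I:C) and 87 for both against thrombin, and 93 were shared. DESeq2 gave 477 genes for both against thrombin and 5 for the interaction, and no low-count filter gave 348 and 7. In 8 libraries these were 373 and 2, with 9 lists for thrombin and 3 for the interaction. With only the compared groups, both against thrombin had 90 genes and both against untreated 611.

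At an adjusted p of 0.01, 379, 526, 288 and 92 genes passed for thrombin, both against untreated, both against poly(I:C) and both against thrombin. At least 2-fold were 56, 136, 225, 132 and 60, with 20 shared, and at least 4-fold induced genes raised further were 6. With an estimated correlation 5, 2, 1 and 0 lists passed for poly(I:C), thrombin, both against poly(I:C) and interaction, and with fry 9 for poly(I:C) and 0 for the interaction. The correlation of the thrombin effects was 0.605 in genes of at least 10 CPM.

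With the replicate block, which pairs libraries of the same number, 454 genes passed for both against poly(I:C) and 132 for both against thrombin. The correlations gave no sign of pairing by number. The 18 pairs of the same number had a median r of -0.0927 and the 36 other pairs 0.0144, and 3 of 12 libraries correlated best with their own number. A pairing is not excluded by this, since the first within-group axis held 45% of the variance and could hide it.

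Leaving out single libraries gave 87 to 166, 400 to 786, 644 to 1209, 279 to 927, 92 to 355 and 1 to 2 genes, 13 to 15, 12 to 17, 9 to 14 and 5 to 12 lists (poly(I:C), thrombin, both against poly(I:C), interaction), 41 to 80 shared genes, 19 to 30 induced genes raised further, and an r of 0.0145 to 0.262.

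Some lists turned direction by camera. With the olfactory receptor covariate the median for both against poly(I:C) was 0.0729 in junction, 0.117 in endothelial identity and -0.0767 in ribosomal protein genes, and the interaction was 0.00483 in receptors, 0.143 in junction, 0.0338 in endothelial identity and -0.0152 in ribosomal protein genes. For mitochondrially encoded genes in both against poly(I:C) the camera direction turned from up to down, while the main median was already -0.0038. That median was -0.188 in 8 libraries and -0.295 without poly(I:C) replicate 3, where the median interaction of these genes was -0.373. These 2 medians reached 0.301 and 0.3 without poly(I:C) replicate 2.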

Other observations

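The 94 tested olfactory receptor genes and the 1086 genes under 1 CPM, chosen as classes after seeing the data, had little change with either treatment alone. Their medians were -0.0713 and -0.0179 (log2) with poly(I:C) and -0.12 and -0.0238 with thrombin, against 0.644 and 0.349 with both treatments versus untreated. Against untreated, genes under 1 CPM made up 0 of 129 calls for poly(I:C), 3 of 619 for thrombin and 12 of 1105 for both (edgeR). They made up 6 of 759 for both against poly(I:C) and 3 of 217 for both against thrombin. The counts of called genes thus rest on more strongly expressed genes. Only 17 of the 94 tested olfactory receptor genes were under 1 CPM. These numbers therefore do not show how far background reads enter the calls.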
